A study of Mus musculus with 6 samples.

How the data were processed

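RNA was measured in 6 libraries of mouse splenic Tregs from bone marrow chimeras, 3 per genotype, which the labels call biological repeats. Cells were rested in medium before lysis, and libraries were made with an unstranded kit, per the labels' protocols. The deposited values are whole-number counts of reads per gene, not normalized. The submitters' processing notes name FastQC, HISAT2, HTSeq, DESeq2 and the build GRCm38, without versions, and the counting mode is not given in the sources used here. No deposited file held a total or an unassigned line, and the same genes stood in the same order in each.

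Of 55573 gene identifiers, 55394 matched the GENCODE M21 annotation of GRCm38, which gave symbols, types and positions, and 179 did not. Library totals ran from 12005273 to 17278521 counts, TMM factors from 0.954 to 1.08, the share of the 10 most abundant genes from 4.54% to 5.95%, and mitochondrial counts from 1.56% to 2.15%. The genes that passed the filter held at least 99.7% of the counts of each library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 5.82 to 106 over genes with at least 20 counts), so no library was taken as a repeat deposit of another. That they are separate biological samples rests on the labels.

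Before the data were examined, the groups, the test, the gene lists, the named-gene rule and the alternatives listed at the end, other than those marked as added, were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by genotype, TMM, robust quasi-likelihood fit with genotype as the only term, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.228. CPM values use TMM-scaled library sizes. A fold against a group with 0 counts uses a floor of 3 counts over the group, and groups with 1 to 3 counts are given as a ratio with an exact 95% interval.

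The genes named are Nfkb2, Nfkb1, Rel, Rela, Relb and Foxp3, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM and no overlap between genotypes, leaving out predicted and clone-named genes and antigen receptor segments, and from each list the up to 4 called members with the smallest p, or otherwise 2 members with the smallest p, given as values; some genes this rule names are not reported here. There were 18 pathway lists and 11 lists of markers of other cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. Tables of genes near Nfkb2 used Fisher's exact test, two-sided, within 10 Mb. Trav segments were examined where a genotype had at least 20 counts, and called low where wild type was under 20% of Nfkb2-/-; the stretch was defined after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

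Replicate numbers are shared between genotypes in the labels, which do not say what a number marks. Deviations from the genotype means correlated at 0.364, 0.267 and 0.111 between same-numbered libraries, each over the limit of 0.1, so the numbers were taken to pair the libraries; Nfkb2-/- replicate 3 correlated more with wild-type replicate 2 (0.251). The unblocked design fixed beforehand remained the main one, with the block as an alternative.

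The code was tested on simulated counts for this comparison, drawn for 13347 genes of which 13089 were tested, with 200 genes changed. It recovered 3 of 49 genes changed 1.5-fold, 20 of 50 changed 2-fold, 40 of 50 changed 4-fold and 50 of 50 changed 8-fold, all in the right direction. Of 123 calls 10 were false, 8.13%, above the nominal 5%. A raised list of 30 genes gave a camera p of 3.99e-46 and an unchanged one 0.271. Simulated genes were drawn independently of each other, whereas the estimated correlation was 0.902 for the B cell markers. The simulation therefore does not test camera's preset correlation on correlated lists.

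Alternatives were RLE and upper-quartile scaling, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, windows of 5 and 20 Mb, an estimated correlation and leaving out each library in turn. Those added after seeing the data were the Y-linked level or the B cell markers as a covariate, X and Y genes left out and a stricter definition of the Trav stretch. Counts per gene without strand cannot separate overlapping or antisense genes, exons, or near-identical paralogs. The B cell list shares Blk with the gamma-delta list, and other lists share members, such as Tnfrsf9 in 4 of them.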

Results

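Regulatory T cells (Tregs), the CD4 T cells that restrain immune responses, were sorted from the spleens of bone marrow chimeras, mice whose blood system was rebuilt from donor marrow, here bi-parental per the labels. Their messenger RNA was counted by RNA sequencing in 3 libraries from wild-type Tregs and 3 from Tregs labelled as knockouts of Nfkb2 (Nfkb2-/-). Nfkb2 is the gene of the NF-kB protein p100 and its processed form p52. The total count per library was 12005273, 14359439 and 12763638 in Nfkb2-/- replicates 1 to 3, and 17278521, 12535383 and 12499343 in wild-type replicates 1 to 3. Of 55573 genes listed, 28459 had no count in any library and 13347 passed the count filter. Levels are given as CPM, counts scaled to the size of the library, and intervals and floors cover counting error only.

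The genotypes differed in the sex-linked transcript Xist, which silences an X chromosome in female cells, and wild-type replicate 1 stood apart from the other libraries. Xist was at 841, 883 and 592 CPM in the Nfkb2-/- libraries and at 1.94, 3.17 and 16.5 CPM in the wild-type libraries. The summed level of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) was 40.1, 138 and 275 CPM in Nfkb2-/- replicates 1, 2 and 3, against 465, 498 and 477 CPM in wild type. Both measures separated the genotypes without overlap and the labels give no donor sex, so sex and genotype are confounded in every comparison here. The split was not clean, since each Nfkb2-/- library held both Xist and Y-linked counts, the latter at 8.34%, 28.7% and 57.3% of the wild-type mean. The 19 B cell markers summed to 788, 910 and 937 CPM in the Nfkb2-/- libraries and to 552, 1966 and 1793 CPM in wild type. Wild-type replicate 1 held 2849 CPM of 4 loci resembling ribosomal RNA, chosen after their values were seen, against 507 to 937 CPM elsewhere. Its log2 CPM correlated across genes with those of the other libraries at r from 0.941 to 0.955, and all other pairs at 0.968 to 0.991, genes not being independent replicates.

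**Figure D1:**
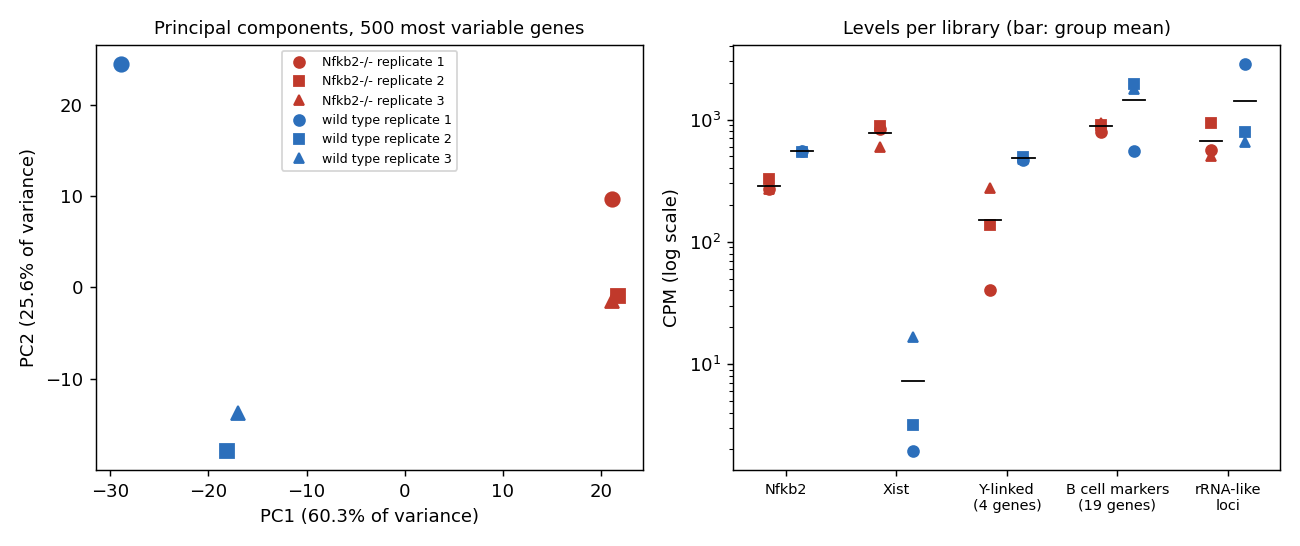
Left, the 6 libraries on principal components 1 (60.3% of the variance) and 2 (25.6%) of the 500 most variable genes; right, CPM on a log axis per library (points) and group mean (bars) of Nfkb2, Xist, the Y-linked genes, the B cell markers and the loci resembling ribosomal RNA. Nfkb2 sits at 268.5 to 324 CPM in the Nfkb2-/- libraries and at 545 to 558 CPM in wild type.

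Nfkb2 itself was lower in every Nfkb2-/- library than in any wild-type library, but not absent. Its level was 288 ± 31.3 CPM (SD, n = 3) in Nfkb2-/- and 553 ± 6.99 CPM (SD, n = 3) in wild type. The counts behind these levels were 3245, 4601 and 3325 in the Nfkb2-/- libraries and 10346, 6888 and 6620 in wild type, so each Nfkb2-/- library kept 48.6%, 58.6% and 49.0% of the wild-type mean. The log2 fold change was -0.94 (SE 0.134, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0203). Nfkb2 (ENSMUSG00000025225) lies at chromosome 19, 46304320 to 46312385 (GRCm38), where it overlaps Psd and the noncoding gene AC114539.1 on the other strand, and the unstranded counts per gene cannot tell these genes or single exons apart. The edgeR adjusted p was 0.125 without Nfkb2-/- replicate 1, 0.118 without replicate 2, 0.176 without replicate 3, 0.0722 without wild-type replicate 2 and 0.0567 without wild-type replicate 3. With the Y-linked level as a covariate, added after seeing the data, it was 0.502.

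Genes higher in Nfkb2-/- Tregs outnumbered those lower: 135 rose and 54 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1816 genes had an unadjusted p under 0.05. More than 2-fold changes were seen in 119 of the genes that rose and 36 of those that fell. In all 189 called genes the CPM of the genotypes did not overlap, as in 20.6% of all genes tested, where chance gives 10%. The called genes included 151 protein-coding genes, 19 T cell receptor segments (14 higher, 5 lower) and 3 immunoglobulin segments, and 9 lay on the X chromosome and 0 on Y.

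The counts of called genes depended on single libraries. Without Nfkb2-/- replicates 1, 2 and 3 in turn, 12, 6 and 11 genes rose and 3, 1 and 1 fell by the same edgeR test. Without wild-type replicate 1, 628 rose and 606 fell, and all 189 genes remained called. Without wild-type replicates 2 and 3, 54 and 56 rose and 9 and 10 fell. With the replicate number as a block 196 rose and 93 fell, and 164 of the 189 remained called. DESeq2 gave 398 and 235, and an edgeR fit with no count filter 292 and 174. With the Y-linked level as a covariate 6 rose and 1 fell, and with the B cell markers as a covariate 1706 rose and 1912 fell, both added after seeing the data.

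The largest rises included genes with almost no count in wild-type Tregs. Hecw1, a ubiquitin ligase gene, had 78 counts over the Nfkb2-/- libraries and 0 over the wild-type libraries, at least 29.0-fold higher against a floor of 3 counts over the group. Tnnt2, which encodes cardiac troponin T, had 102 counts against 1, a ratio of 114 (95% counting interval 20.0 to 4544), and Rnf165, another ubiquitin ligase gene, 102 against 3, a ratio of 38.0 (12.6 to 187). Lad1, which encodes the anchoring filament protein ladinin, rose from 0.906 ± 0.344 CPM in wild type to 18.6 ± 4.4 CPM (SD, n = 3 each), a log2 fold change of 4.31 (SE 0.333, edgeR adjusted p = 0.00272). Dscam, a neural cell adhesion gene, rose from 13.3 ± 9.52 to 177 ± 28.5 CPM (log2 fold change 3.76), and Sh3pxd2b, an adaptor of podosomes, from 3.0 ± 3.01 to 46.0 ± 11.3 CPM (3.86). Lad1 and Tnnt2 lie within 10 Mb of Ptprc on chromosome 1, a window taken up at the end of the report. Xist rose by a log2 fold change of 6.78, with 772 ± 157 CPM against 7.19 ± 8.05 CPM. Log2 fold changes of Mark1 (a microtubule kinase), Thsd7a, Tmem151b, St6galnac1 (a sialyltransferase) and Papln were 5.10, 4.51, 4.26, 3.67 and 3.54. With no count filter the edgeR adjusted p was 0.103 for Xist, 0.176 for Sh3pxd2b and 0.246 for Dscam.

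Among the largest falls were a protease gene, a B cell receptor gene and a gene of lipid synthesis. Ctse, which encodes the aspartic protease cathepsin E, fell from 180.1 ± 23.5 CPM in wild type to 21.1 ± 3.07 CPM (SD, n = 3 each), a log2 fold change of -3.09 (SE 0.168, edgeR adjusted p = 0.000653). Cd55, which protects cells from complement, fell from 84.9 ± 13.6 to 22.8 ± 5.46 CPM (log2 fold change -1.90). Scd1, a fatty acid desaturase, fell from 32.6 ± 20.3 to 3.45 ± 1.61 CPM (log2 fold change -3.24, edgeR adjusted p = 0.0286). Ctse and Cd55 lie within 10 Mb of Ptprc on chromosome 1, and Scd1 and Sfxn2 within 10 Mb of Nfkb2, windows taken up at the end of the report. The B cell receptor gene Cd79a had a log2 fold change of -2.70. Others were B3gnt7, a glycosyltransferase (-3.33), Mef2c, a transcription factor (-2.45), Snx8, a sorting nexin (-2.03), Sfxn2, a mitochondrial carrier (-2.01), Dok3, a signalling adaptor (-1.89), Rab4a, an endosomal GTPase (-1.83), and Ifi214, an interferon-inducible gene (-1.70). In the blocked fit the edgeR adjusted p was 0.0514 for B3gnt7 and 0.0571 for Ifi214, with no count filter it was 0.126 for Scd1, and 6 of these genes passed 0.05 in edgeR but not in limma-voom (limma-voom adjusted p: B3gnt7 0.0637, Scd1 0.0565, Mef2c 0.0761, Snx8 0.0658, Dok3 0.0578, Ifi214 0.0578). Of 38 called genes named by the rule fixed beforehand, 33, 36 and 34 lost the call without Nfkb2-/- replicates 1, 2 and 3, and 21 and 23 without wild-type replicates 2 and 3.

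Among genes of effector Tregs, the activated Tregs that settle in tissues, single members were higher in Nfkb2-/- cells. Of 33 tested, 6 rose and 0 fell, or 14 and 1 adjusted over the list alone, and 29 had a positive log2 fold change (median 0.48). Il1rl1, the receptor of interleukin-33, rose from 91.1 ± 12.9 CPM in wild type to 263 ± 45.1 CPM (SD, n = 3 each), a log2 fold change of 1.53 (SE 0.171, edgeR adjusted p = 0.0102). Rora, a nuclear receptor, rose from 171 ± 29.2 to 425 ± 29.6 CPM (log2 fold change 1.32), Tnfrsf9, the costimulatory receptor 4-1BB, from 423 ± 32.4 to 877 ± 44.4 CPM (1.05), and Klrg1, a receptor of differentiated T cells, from 9.28 ± 2.16 to 26.2 ± 4.42 CPM (1.5). Gata3, a transcription factor of type-2 responses, and Epas1, a hypoxia-inducible factor named here after its value was seen, had log2 fold changes of 0.80 and 1.30. The list ranked above other genes (camera adjusted p = 6.05e-13, but adjusted p = 0.581 with an estimated correlation), and fry gave an adjusted p of 0.311 for a change one way. Without Nfkb2-/- replicates 1, 2 or 3, 0 of the 6 genes passed edgeR's threshold, without wild-type replicate 2 or 3, 2 did, and 0 did with the Y-linked covariate, while all 6 kept a positive log2 fold change in each of these fits. Without each library in turn it ran from 1.38 to 1.62 for Il1rl1, 1.21 to 1.45 for Rora and 1.00 to 1.11 for Tnfrsf9, and the list median with the Y-linked covariate was 0.63. Without wild-type replicate 1, 13 members rose and 3 fell, by DESeq2 11 rose and 1 fell, and in the blocked fit 9 rose and 1 fell. The same Nfkb2-/- libraries held more Xist and, against wild-type replicates 2 and 3, fewer B cell marker counts.

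Few Treg identity genes were called. In the Treg core list 1 of 28 rose (Tnfrsf9) and 0 fell, or 6 and 0 adjusted over the list alone, with a median log2 fold change of 0.38 (camera adjusted p = 3.43e-06, adjusted p = 0.581 with an estimated correlation). Foxp3, the transcription factor that defines Tregs, was at 525 ± 67.4 CPM in Nfkb2-/- and 505 ± 109 CPM in wild type (SD, n = 3 each; log2 fold change 0.06, edgeR adjusted p = 0.935), and its counts share an interval with the noncoding gene Flicr. With each library left out in turn its log2 fold change ran from -0.08 to 0.24. Of 23 genes of resting T cells 0 rose and 1 fell, or 0 and 9 adjusted over the list alone, with a median of -0.73 (camera adjusted p = 5.77e-09, adjusted p = 0.581 with an estimated correlation, fry adjusted p = 0.211 for a change one way). The B cell markers had a median of -1.79 in the same comparison. The member that fell was Il6ra, a receptor chain of interleukin-6, from 158 ± 21 to 61.8 ± 14.5 CPM (log2 fold change -1.36, edgeR adjusted p = 0.0201). The number of resting genes that fell was 8 without wild-type replicate 1, 0 without Nfkb2-/- replicates 2 or 3 or wild-type replicate 3, 4 in the blocked fit, 8 by DESeq2, 6 with no count filter and 0 with the Y-linked covariate, where the list median was -0.94. Of suppressor molecules, 0 of 19 rose or fell, or 5 and 0 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00115, adjusted p = 0.746 with an estimated correlation, and 0.140 without wild-type replicate 1). Log2 fold changes were 1.43 for Havcr2, which encodes the inhibitory receptor TIM-3, and 0.90 for Itgb8, an integrin chain that activates TGF-beta, with edgeR adjusted p of 0.0561 and 0.115, or 0.0312 and 0.0454 in the blocked fit, which called 2 suppressor genes higher.

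**Figure D2:**
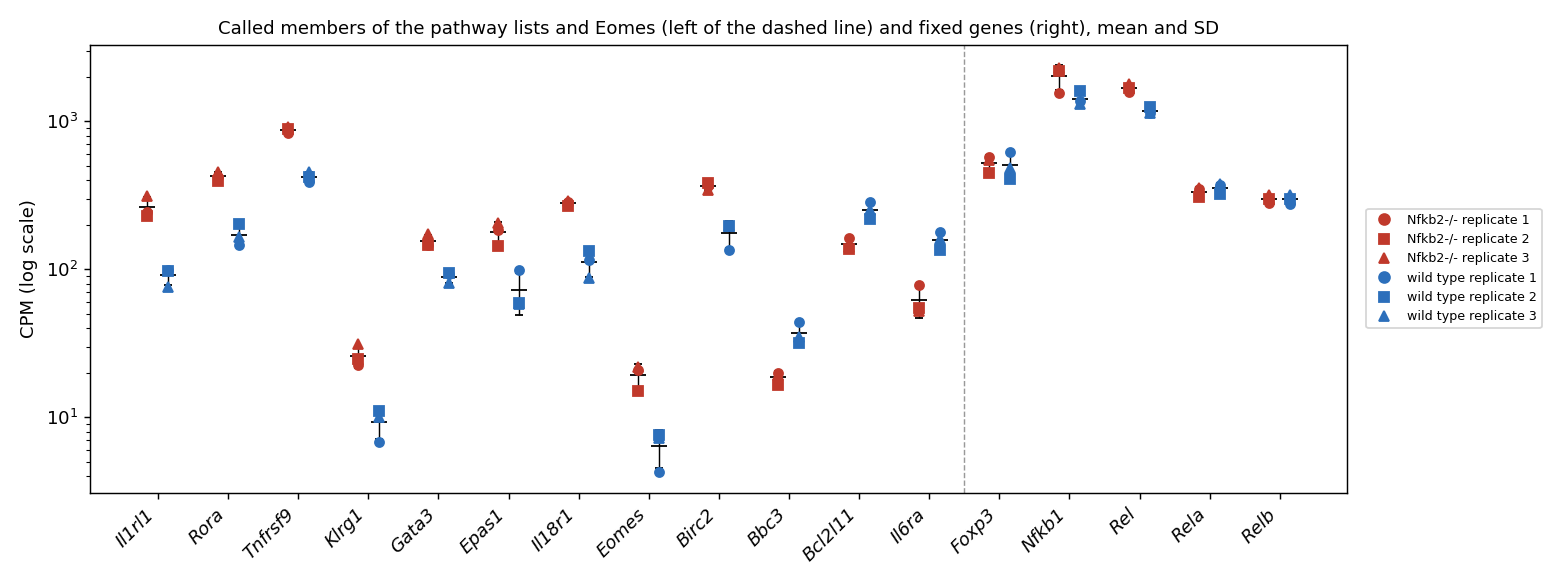
CPM on a log axis of called list members and of fixed genes, a point per library with the mean and SD of each genotype (n = 3). Il1rl1, Rora, Tnfrsf9 and Klrg1 lie higher in every Nfkb2-/- library than in any wild-type library, and Foxp3 averages 525 and 505 CPM.

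The other NF-kB subunit genes were not called. Log2 fold changes were 0.50 for Nfkb1, 0.52 for Rel, -0.09 for Rela and 0.01 for Relb (edgeR adjusted p = 0.319, 0.161, 0.845 and 0.983), while DESeq2 gave Rel an adjusted p of 0.0117. Relb ran from -0.04 to 0.06 without each library in turn. Of 26 NF-kB subunits and regulators, 1 rose and 0 fell, or 3 and 0 adjusted over the list alone (median 0.07, camera adjusted p = 0.0387, adjusted p = 0.746 with an estimated correlation). That camera value was 0.0570 without Nfkb2-/- replicate 3, 0.210 without wild-type replicate 1 and 0.0624 in limma-voom. The member that rose was Birc2, an inhibitor-of-apoptosis protein of the NF-kB pathway, from 176 ± 35.7 to 364 ± 21.1 CPM (SD, n = 3 each; log2 fold change 1.05, edgeR adjusted p = 0.0319), and the blocked fit called 2 higher. Of 40 NF-kB target genes, 1 rose (Tnfrsf9) and 0 fell, or 6 and 1 adjusted over the list alone and 2 and 1 in the blocked fit (median 0.12, camera adjusted p = 0.0536). In the TNF receptor family 1 of 25 rose, again Tnfrsf9, and 0 fell, or 2 and 2 adjusted over the list alone and 1 and 1 in the blocked fit; the median was -0.02 and the mean -0.05, while camera ranked the list up (adjusted p = 0.643).

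Helper and survival genes moved in a few members. Of 19 helper T cell regulators and cytokines, 2 rose and 0 fell, or 4 and 1 adjusted over the list alone and 3 and 0 in the blocked fit: Gata3, and Il18r1, a receptor chain of interleukin-18, which rose from 112 ± 23.2 to 281 ± 12.5 CPM (SD, n = 3 each; log2 fold change 1.32, edgeR adjusted p = 0.0157). The helper median was -0.03 while camera ranked the list up (adjusted p = 0.110). Of 24 cell survival and death genes, 1 rose and 2 fell, or 5 and 3 adjusted over the list alone and 3 and 2 in the blocked fit, with a median of -0.06 against a mean of 0.06 and a camera rank up (adjusted p = 0.643). Birc2, which opposes cell death, rose, and the cell death genes Bbc3 and Bcl2l11, which encode PUMA and BIM, fell from 37.0 ± 6.51 to 18.7 ± 1.78 CPM and from 252 ± 34.5 to 147 ± 13.2 CPM (log2 fold changes -0.99 and -0.78, edgeR adjusted p = 0.0396 and 0.0483). Over all lists, 472 members were tested, of which 10 rose and 6 fell. The members called over all lists numbered 1, 0 and 0 without Nfkb2-/- replicates 1, 2 and 3, 107, 4 and 3 without wild-type replicates 1, 2 and 3, 36 in the blocked fit, 63 by DESeq2 and 0 with the Y-linked covariate.

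Several pathways gave no called member in the unblocked fit. Glycolysis genes had 0 of 22 called, 0 adjusted over the list alone, yet 20 had a positive log2 fold change (median 0.31, camera adjusted p = 0.0175, adjusted p = 0.933 with an estimated correlation). The glycolysis camera value was 0.556 without Nfkb2-/- replicate 1, 0.514 without wild-type replicate 1, 0.0598 in the blocked fit and 0.239, with the direction turned, with the Y-linked covariate. Among them Hk2, a hexokinase, had a log2 fold change of 1.34 and Pgam1, a mutase, 0.48. Chemokine and homing receptors had 0 of 25 called, or 4 higher and 2 lower adjusted over the list alone and 2 and 1 in the blocked fit (median 0.14, camera adjusted p = 0.0536), with Gpr15, a gut-homing receptor, at 1.27 (edgeR adjusted p = 0.0558, 0.0332 blocked) and Ccr3 at 1.21. Interferon response genes had 0 of 33 called, or 1 higher and 1 lower adjusted over the list alone (median -0.12, camera adjusted p = 0.416), with Gbp2, an interferon-induced GTPase, at -1.08. T cell receptor signalling genes had 0 of 27 called, or 1 higher and 0 lower adjusted over the list alone (median 0.01, camera adjusted p = 0.721), with Trat1 at 0.85 and Cd28 at -0.52.

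For 5 further lists neither adjustment called a member. These were cell cycle genes (32 tested, median log2 fold change 0.07, Tk1 0.29 and Ube2c -0.40), immediate-early and heat-shock genes (30 tested, median 0.16, Fosl2 0.59 and Zfp36 -0.82), oxidative phosphorylation genes (34 tested, median 0.08, Sdhb 0.32 and Uqcrc1 0.16), mitochondrially encoded genes (11 tested, median -0.18, mt-Nd2 -0.55 and mt-Nd1 -0.42) and MHC class I presentation genes (19 tested, median 0.02). Their camera adjusted p was 0.806, 0.561, 0.348, 0.0969 and 0.735 in that order. H2-Q6 and H2-Q7, near-identical paralogs whose counts are uncertain, had log2 fold changes of 0.34 and 0.28. Leaving out 1 library brought some of these lists past camera's threshold: heat-shock genes at adjusted p = 0.0186 with the direction turned without wild-type replicate 1 and at 0.000911 without wild-type replicate 3, oxidative phosphorylation at 0.00398 without wild-type replicate 3, and mitochondrial genes at 0.00252 without Nfkb2-/- replicate 3 and 0.0494 without wild-type replicate 2.

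**Figure D3:**
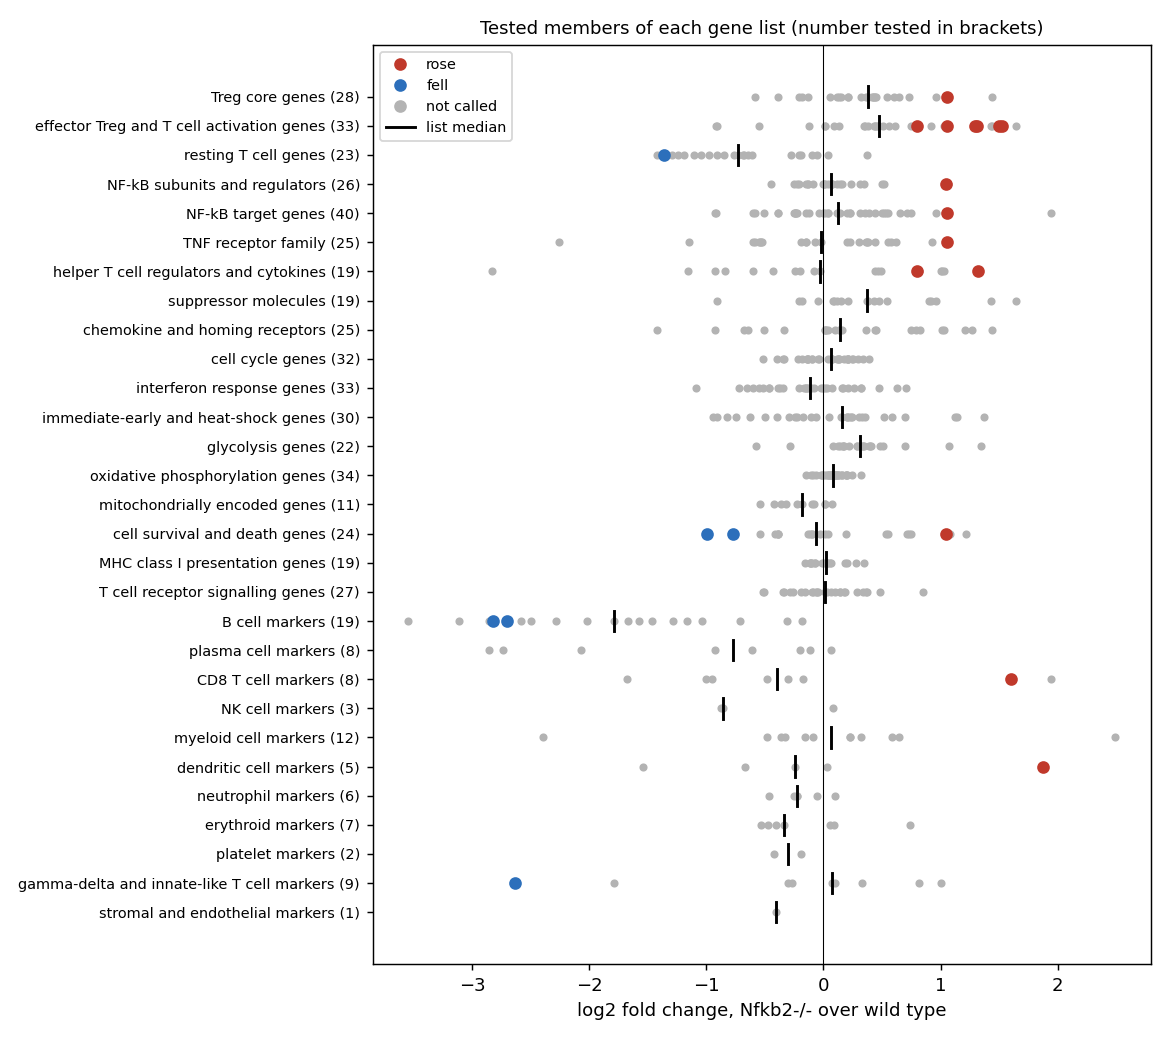
Log2 fold change, Nfkb2-/- over wild type, of the tested members of the 29 gene lists (points, called members coloured; bars are medians). Effector Treg genes have a median of 0.48, resting T cell genes -0.73 and B cell markers -1.79.

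B cell markers had lower mean levels in Nfkb2-/- than in wild type, although wild-type replicate 1 held fewer of their counts in sum (552 CPM) than any Nfkb2-/- library. All 19 had a negative log2 fold change (median -1.79), and 0 rose and 2 fell, or 0 and 12 adjusted over the list alone and 0 and 8 in the blocked fit (camera adjusted p = 1.72e-16, adjusted p = 0.581 with an estimated correlation). Cd79a fell from 34.7 ± 14.2 to 5.33 ± 2.08 CPM (SD, n = 3 each; edgeR adjusted p = 0.0230). Without wild-type replicate 1 all 19 fell, and without any other library 0 were called. Plasma cell markers had 0 of 8 called, or 0 higher and 3 lower adjusted over the list alone and 0 and 1 in the blocked fit (median -0.77, camera adjusted p = 0.0165, adjusted p = 0.746 with an estimated correlation), with the antibody chains Iglc1 at -2.73 (edgeR adjusted p = 0.0796, 0.0373 blocked) and Igha at -2.85. The plasma camera value was 0.136 without wild-type replicate 2, 0.0618 in limma-voom, 0.0834 with the Y-linked covariate and 0.742, with the direction turned, with the B cell covariate.

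Markers of other cells moved in single members. Of 8 CD8 T cell markers 1 rose and 0 fell, or 2 and 0 adjusted over the list alone and in the blocked fit: Eomes, a transcription factor, rose from 6.39 ± 1.85 to 19.3 ± 3.73 CPM (SD, n = 3 each; edgeR adjusted p = 0.0364). That list's median was -0.39 and its mean -0.13, while camera ranked it up (adjusted p = 0.721). Of 5 dendritic cell markers 1 rose and 0 fell, the same counts adjusted over the list alone: Zbtb46, a transcription factor, from 27.8 ± 13.0 to 103 ± 15.8 CPM (edgeR adjusted p = 0.0355), with a list median of -0.24 and a camera rank up (adjusted p = 0.395). Of 9 gamma-delta and innate-like T cell markers 0 rose and 1 fell, the same counts adjusted over the list alone: Cd163l1, a scavenger receptor, had 8 counts over the Nfkb2-/- libraries and 59 over wild type (log2 fold change -2.63, edgeR adjusted p = 0.0496, or 0.0567 blocked, 0.0615 in limma-voom and 0.050 with X and Y genes left out). That list's median was 0.07, its mean -0.30 and its camera rank down (adjusted p = 0.806).

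The remaining marker lists had 0 called members by either adjustment. Of 12 myeloid markers (median log2 fold change 0.07, camera adjusted p = 0.643), Vcam1 was at 2.49 and Ly86 at -2.39. Of 6 neutrophil markers (median -0.23 with a camera rank up, adjusted p = 0.806), Camp was at -0.46 and Ngp at -0.25, and of 7 erythroid markers (median -0.33, camera adjusted p = 0.769), Car2 was at 0.74 and Hbb-bs at -0.53. Lists of under 5 tested members were not tested as sets: 3 NK cell markers (median -0.85, Fcer1g -0.87 and Tyrobp -0.85), 2 platelet markers (Itgb3 -0.19 and Itga2b -0.42) and 1 stromal marker (Pecam1 -0.41). Myeloid markers reached a camera adjusted p of 0.0196 without wild-type replicate 2, and neutrophil markers 0.00979 with the direction turned without wild-type replicate 3.

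Of 26 lists tested as sets, camera with its preset correlation placed 5 up and 3 down, and 0 held with an estimated correlation. In the other splits of the libraries, 3 against 3, the preset correlation called 9 to 19 lists. The self-contained fry test, which compares a list with no other genes, gave after adjustment 0 lists for a change one way on balance and 13 for changes in either direction. The camera calls moved with single libraries also for lists not called: without Nfkb2-/- replicate 1, NF-kB target genes were at adjusted p = 0.0201 and helper genes at 0.00719; without replicate 2, chemokine receptors were at 0.0294. Without wild-type replicate 1, interferon genes were at 0.00225. Without wild-type replicate 2, NF-kB target, helper and chemokine receptor genes were at 0.0149, 3.91e-05 and 0.00771, and without replicate 3 at 0.00398, 0.0470 and 0.0196. With no count filter, NF-kB target, helper, chemokine receptor and mitochondrial genes were at 0.0233, 0.0136, 0.0225 and 0.0486, and helper genes at 0.0205 with the 1 CPM filter. With the Y-linked covariate, NF-kB target, helper, cell cycle, myeloid and dendritic genes were at 0.00159, 0.00457, 0.0133, 0.0225 and 0.0118, and with X and Y genes left out, NF-kB target and chemokine receptor genes were both at 0.0496. With the B cell covariate 18 lists were called.

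T cell receptor alpha variable (Trav) segments of a stretch of chromosome 14 had few counts in wild-type Tregs. The stretch ran from 53042428 to 53710419 (GRCm38, 668 kb), and was defined, after seeing the data, as the longest run of examined segments under 20% of the Nfkb2-/- level, 32 of 54, with 0 such segments outside it. It held 76.8% ± 0.253 (SD, n = 3) of Trav counts in Nfkb2-/- libraries (77.1%, 76.8% and 76.6%) and 5.83% ± 6.58 in wild type (2.06%, 1.99% and 13.4%), a difference that was not tested because it defined the stretch. Under a stricter definition of the stretch, chosen after seeing the data, the mean shares differed by 39.9 percentage points. Segments upstream were at 8.30 ± 0.856 CPM in Nfkb2-/- and 36.9 ± 8.28 CPM in wild type, and those downstream at 7.84 ± 1.42 and 8.32 ± 3.19 CPM. The constant gene Trac was at 323 ± 30.8 and 279 ± 82.2 CPM. The segments resemble each other closely, so counts of single segments are uncertain.

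**Figure D4:**
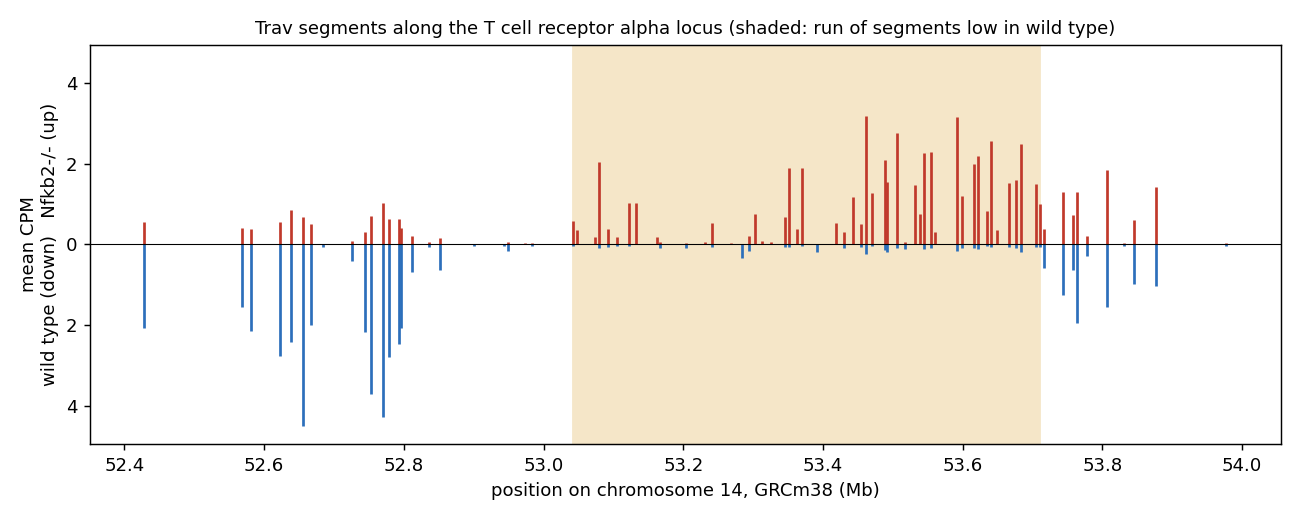
Mean CPM of each Trav segment along chromosome 14 (GRCm38), Nfkb2-/- upwards and wild type downwards, with the stretch from 53042428 to 53710419 shaded. Inside it the summed level is 53.5 CPM in Nfkb2-/- and 3.43 CPM in wild type.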

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

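All tests in this part were chosen after the result was seen.

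Data outside the main test held a signal above the control level: 39 Trav segments of the stretch removed by the count filter had 403 counts over the Nfkb2-/- libraries and 56 over wild type, 10.3 against 1.32 CPM. Of these, 10 helped to define the stretch by their low wild-type level, and the 29 that did not held 124 against 43 counts.

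The Trav segments low in wild type formed a single run of 32 among 54 examined, which is how the stretch was noticed and delimited, so that run tests no explanation. Segment use graded along the locus by genotype would need a steady trend. Over 3 parts of 18 examined segments each, divided by position alone, the Nfkb2-/- level over wild type was 0.317, 22.99 and 3.06. The lowest ratio between single libraries in the middle part (9.87) lay above the highest of the last (5.21). The counts as assigned thus had no steady trend. But the middle part lay wholly inside the run already seen, and reads shared between segments could shift these ratios, so graded use itself was not excluded. A donor haplotype that lacks or differs over the stretch stays open. The 29 segments that took no part in defining it were at 9.13%, 15.1% and 80.8% of the Nfkb2-/- mean in the wild-type libraries, a mean of 34.99%. The 80.8% rests on 32 counts in wild-type replicate 3, of which Trav3n-3 held 12 and Trav7-2 held 7. Both had 0 counts in Nfkb2-/- and shared 100% of their 31-base words with other Trav segments, so the origin of these reads is uncertain. Reads shared between near-identical segments stay open too: of 7 examined segments with under 5% of their 31-base words in any other Trav segment, 1 was low in wild type, and only that 1 lay in the stretch. Expanded clones were not excluded, as the most abundant segment took 8.48% to 11.5% of a wild-type library's Trav counts and 4.45% to 4.94% in Nfkb2-/-, no DNA sequence of the donors was tested, and genotype and donor are confounded.

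Nfkb2 kept a mean of 52.0% ± 5.67 (SD, n = 3) of its wild-type level in the Nfkb2-/- libraries. Cells of the wild-type donor would bring their Trav counts: at each library's Nfkb2 share, upstream segments would reach 17.9, 21.6 and 18.1 CPM, but they were at 7.53, 9.22 and 8.14 CPM, a mean of 8.30. This assumes that such cells carry the Trav pattern of the wild-type libraries, and the test replaced one on Y-linked levels (8.34%, 28.7% and 57.3% of wild type) after those were seen. Transcript from the part of the gene left by the targeting cannot be told apart from other sources, because counts per gene do not separate exons, and cells of the recipient were not tested.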

How the results depend on the processing

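The covariates, the X and Y fit and the stricter Trav definition are tests chosen after the data were seen; all others were planned. Every called gene kept its direction wherever it was tested, RLE and upper-quartile scaling ended no named call, and the block changed no other call of a named gene or set test than those given in the report, which gives its counts by list. Of the alternative values, 1314 stayed on their side of the threshold or within the spread, 234 lost and 107 gained a call or count, 62 turned direction and 1 moved. Named genes not called in the report passed in 11 cases by DESeq2, 6 with no filter, 4 with the block, 2 in limma-voom, 12 with the B cell covariate and 14 without wild-type replicate 1. The cause of these changes was not tested.

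By setting, genes that rose and fell, list members called and the odds ratio near Nfkb2 were 398, 235, 63 and 2.28 by DESeq2, 292, 174, 40 and 2.75 with no filter (neutrophil camera adjusted p 0.817), and 0.992 for the odds ratio in limma-voom, with Tyrobp 0.0091, Ngp 0.37 and gamma-delta camera adjusted p 0.834. The block gave 93 lower, 36 members and Ngp 0.16, the 1 CPM filter a gamma-delta camera adjusted p of 0.590, and an estimated correlation 0 lists. The Y-linked covariate, lower in every Nfkb2-/- library, gave 6, 1, 0 and 0, Nfkb2 -0.90 (edgeR adjusted p = 0.502), Foxp3 -0.0501, Hbb-bs 0.19, Tyrobp 0.52, Ube2c 0.0145, and camera adjusted p of 0.855 (MHC class I), 0.971 (T cell receptor signalling), 0.161 (erythroid), 0.268 (gamma-delta) and 0.239 (glycolysis). The B cell covariate gave 1706, 1912, 183 members and 18 lists, Camp 0.0408, Fcer1g 0.41, Foxp3 -0.34, Igha 0.97, Ly86 0.20, Tyrobp 3.33, and camera adjusted p of 0.794 (B cell), 0.635 (erythroid), 0.182 (gamma-delta and interferon) and 0.742 (plasma). The stricter definition put the difference in Trav share at 39.9 percentage points.

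Without each library in turn, 6 to 628 genes rose, 1 to 606 fell, 0 to 107 members and 7 to 14 lists were called, and the odds ratio ran from 0 to 3.17. Log2 fold changes ran from -1.03 to -0.90 (Nfkb2), -0.0433 to 0.0585 (Relb), -0.0807 to 0.24 (Foxp3), -1.48 to 0.91 (Tyrobp), -0.94 to 0.42 (Camp), -0.79 to 0.52 (Ngp) and -0.62 to 0.0065 (Itga2b). Set-test adjusted p ran from 0.00398 to 0.992 (NF-kB targets), 0.297 to 0.719 (TNF receptors), 3.91e-05 to 0.992 (helper), 0.133 to 0.921 (cell cycle), 0.00225 to 0.958 (interferon), 0.000911 to 0.658 (heat-shock), 0.00398 to 0.540 (oxidative phosphorylation), 0.210 to 0.918 (MHC class I), 0.167 to 0.918 (T cell receptor signalling), 0.190 to 0.992 (CD8), 0.0196 to 0.921 (myeloid), 0.142 to 0.992 (dendritic), 0.00979 to 0.992 (neutrophil), 0.258 to 0.884 (erythroid) and 0.514 to 0.868 (gamma-delta).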

Other observations

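The limit set on the share of linked DNA and the tests of wild-type replicate 1, donor sex and other cells were chosen after the result was seen, while Fisher's test near Nfkb2 and the splits were planned. The genes of the next 2 paragraphs were chosen after their values were seen.

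Ligands of CD28 changed in opposite directions. Cd80 rose from 13.3 ± 1.99 to 29.9 ± 1.62 CPM and Cd86 fell from 59.7 ± 1.05 to 33.5 ± 1.02 CPM (SD, n = 3 each; edgeR adjusted p = 0.0201 and 0.0189). Il18rap, the partner of Il18r1 in the interleukin-18 receptor, rose by a log2 fold change of 1.43, and Tnfsf15, a TNF family cytokine, by 3.38. Il1rl1, Il18r1 and Il18rap lie close together on chromosome 1, between 40429570 and 40551705 (GRCm38), so their rises may not be separate changes. Clusters of called genes outside the windows around Nfkb2 and Ptprc were not tested. Bhlhe40, a transcription factor of activated T cells, rose from 433 ± 75.8 to 1593 ± 171 CPM (edgeR adjusted p = 0.00807). The lymphoid transcription factors Ikzf3 and Gfi1 had log2 fold changes of -0.92 and -0.82, and the interferon-induced GTPases Ifi47 and Gbp2b -0.98 and -1.42.

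Pcyt1a, a gene of phosphatidylcholine synthesis, rose from 34.9 ± 5.28 to 244 ± 31.5 CPM and Asb2, part of a ubiquitin ligase that degrades filamins, from 12.9 ± 1.94 to 89.2 ± 12 CPM (SD, n = 3 each; edgeR adjusted p = 0.000802 and 0.000873). Ttn, the giant muscle protein gene, rose from 31.6 ± 11.1 to 175 ± 29.1 CPM, Myo3b by a log2 fold change of 1.70 and Dst, a cytoskeletal linker, by 1.25. The receptors Axl, Kit and Itgb5 rose by 1.75, 1.5 and 2.21.

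Between the genotypes 189 genes and, with camera's preset correlation, 8 lists were called, 0 of them with an estimated correlation. The 3 libraries against 3 make 10 splits, too few for a share under 0.05: for genes 1 split was as large (highest other 0, also among the 4 that part all pairs), and for lists all 10 (highest other 19). The other splits each called more lists than the genotypes, 9 to 19, and 0 genes. DNA linked to the targeted locus held 3 of 188 called genes within 10 Mb of Nfkb2, 1.6% (exact 95% interval 0.330 to 4.59%). That share argues against linked DNA as the main source of the calls. The odds ratio was 1.56 (0.316 to 4.74, Fisher's exact p = 0.448). These 3 genes were Sfxn2, Scd1 and Pdcd4, at 0.27, -1.91 and 7.59 Mb from Nfkb2, and linked DNA was not excluded for any of them. An excess near the locus stays open, with Fisher's exact p of 0.00346 with no count filter (odds ratio 2.75), 0.00975 by DESeq2 (2.28) and 0.0103 without wild-type replicate 1 (1.91), and up to 1 in other settings. Around Ptprc on chromosome 1, a locus chosen after the calls were seen, 6 of 95 genes within 10 Mb were called (odds ratio 4.84, 1.71 to 11.2, Fisher's exact p = 0.00222, unadjusted), with an odds ratio of 4.43 (0.874 to 13.9, p = 0.0350) within 5 Mb and 2.63 (0.938 to 5.96, p = 0.0325) within 20 Mb.

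For the effector Treg genes, all 6 remained called without wild-type replicate 1. They were chosen by their call with that library included. In all 189 called genes the genotypes did not overlap, and all 189 remained called without it. The test could therefore hardly show wild-type replicate 1 alone as the source, and no conclusion is drawn from it. Cells that are not T cells in the wild-type libraries would lower T cell genes there along with the effector list (median log2 fold change 0.48), but the 27 T cell receptor signalling genes had a median of 0.0101 (SD 0.311), below it by more than their spread. Other T cells there cannot be told apart from a change in the Tregs, since 24 Treg core genes outside the effector list had a median of 0.373 (SD 0.396), near that of the list. Donor sex cannot be told apart from genotype: with the Y-linked level as a covariate 0 of the 6 were called, as the median SE of the 33 members went from 0.251 to 0.420 while their median log2 fold change went from 0.48 to 0.63. A response of the cells to loss of Nfkb2 remains a hypothesis, because neither donor sex nor donor haplotype can be separated from genotype.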
